A study of Mus musculus with 2 samples.

How the data were processed

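Dimethylation of lysine 79 of histone H3 (H3K79me2) was measured by chromatin immunoprecipitation and sequencing in mouse embryonic fibroblasts, in 1 group of 2 libraries. Per the labels' protocols, cells were grown in DMEM with 10% FBS, chromatin was sonicated to a mean of 500 bp, and the precipitated DNA went through 18 cycles of LM-PCR. The libraries differ, per the labels, in flow cell, date and the size range cut from the gel, which ran from 150 to 350 bp for replicate 1 and from 150 to 300 bp for replicate 2. Replicate numbers follow the order of the records and carry no other meaning. No source used here says whether the libraries came from separate cultures, so their spread may be technical. No input library and no second condition were analysed here.

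The authors deposited 1 list of read positions per library. Per the file headers, reads were placed on mouse build mm8 with Bowtie, set to report up to 2 placements (-k 2, -m 2), with up to 2 mismatches in a seed of 36 bases (-n 2, -l 36), a limit of 70 on summed mismatch quality (-e 70) and the best placements first. The submitters' processing notes name the same aligner and build. Its version is not given in the sources used here. Each line is a signed position, the sign giving the strand, and the deposited lists separate reads with 1 placement from reads with 2. The number was read as the leftmost base counted from 0 on both strands, because on both strands of the autosomes the lowest positions were 3000000 in replicate 1 and 3000020 in replicate 2, where the sequence begins after the gap at the chromosome start. The lists hold no sequences and no region calls.

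Unless said otherwise, counts were computed from the reads with 1 placement, keeping 1 read per position and strand. The 5′ end, with a read length of 36 bases taken from the header, was moved 60 bp downstream. Reads were counted in 1 kb bins, and the background of a library was the median of its 10 kb bins that held reads. A bin was called when its Benjamini-Hochberg adjusted p in a one-sided Poisson test was below 0.001 and its count was at least 3 times the background. Called bins were joined over gaps of up to 2 kb, and a region needed at least 2 bins. The smallest bin count called was 20 reads in replicate 1 and 12 in replicate 2. Regions of the libraries that overlapped by at least 1 bp were merged into shared regions. Fold is the read count plus 1 over the expected background count plus 1, and levels are log2 folds given as mean ± SD over the 2 libraries. Coordinates are those of mm8, counted from 1.

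Counts of both libraries in all regions called in either were compared with an exact two-sided binomial test against the ratio of the libraries' totals over those regions, for regions with at least 20 reads, with a Benjamini-Hochberg adjusted p below 0.01. This compares 2 libraries, not conditions. Chance overlap came from moving the regions of replicate 2 along each chromosome in 100 sets. Poisson tests and binomial intervals cover counting error only, because reads without molecular identifiers are not independent molecules. Without an input library, copy number and collapsed repeats enter each fold.

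Poisson counts were simulated over 2462530 autosomal bins, with the local density of each library capped at 1.5 times background. Regions of 10 kb at 6-fold were all recovered in both libraries (50 of 50 each). At 4-fold, 50 of 50 were recovered at the depth of replicate 1 and 12 of 50 at that of replicate 2. At 3-fold the numbers were 13 and 1, at 2-fold 0 and 0, and no region was called outside the planted ones. The count threshold was set anew on the simulated bins, which held few enriched ones, so it can be stricter than that of the calls reported. The recovered numbers therefore do not give the sensitivity of those calls. With the density capped, the absence of other calls does not cover false calls from repeats, copy number or local excess. In the test between libraries, simulated over 28150 regions, 18 of 100 changes of 1.5-fold and 44 of 100 changes of 2-fold were recovered, with 0 calls among unchanged regions.

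The design fixed before the data were examined called for tests of genes and gene lists if gene coordinates of the build were at hand. The gene table used here is of another build, GRCm38.p6, and no coordinates were converted, so regions took the place of genes, as that design provided. Regions are therefore given by position, with no gene or exon assigned. The regions named are the 20 with the highest mean log2 fold, the 5 longest, and the 3 with the largest ratio in each direction between the libraries among those with at least 50 reads. Alternatives changed the treatment of repeated starts, the shift, the background, depth, thresholds, bin, gap and overlap, or left out a library. Analyses ran in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1, and plots in matplotlib 3.10.9.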

Results

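H3K79me2, the mark that the methyltransferase DOT1L places on transcribed chromatin, was mapped in 2 libraries from mouse embryonic fibroblasts, primary connective tissue cells grown from embryos. Replicate 1 held 20110155 reads with 1 placement and replicate 2 held 13850845. Repeated starts made up 15.2% of these reads in replicate 1 and 5.62% in replicate 2, which left 17040511 and 13071761 distinct starts on the nuclear chromosomes. Background was 6.5 reads per kb in replicate 1 and 3.1 reads per kb in replicate 2. The most frequent offset between strands corresponds to a fragment length of 96 bp in replicate 1 and 50 bp in replicate 2. That peak was 1.43 and 2.58 times the level at distant offsets. Per the labels inserts ran from 50 to 200 nt, so the value of replicate 2 lies at their lower limit. Both lengths are rough estimates. Both libraries belong to the same group, so the questions the design allows are where the mark lies and how far the libraries match.

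Calls of both libraries met in 4938 merged regions, which cover 142.8 Mb or 5.43% of the 2631 Mb spanned by reads. Of that length 53.04 Mb (37.1%) was called in both libraries, 38.1% in replicate 1 and 98.99% in replicate 2, so the extent of these shared regions is set largely by replicate 2. Their median width was 19 kb with a 90th percentile of 62 kb, and the part called in both was 6 kb at the median and 24 kb at the 90th percentile. In 3973 of them the merged width was 10 kb or more, in 162 it was 100 kb or more, and in 75 it was 3 kb or less. Median fold over background was 2.53 in replicate 1 and 8.16 in replicate 2. In 4909 shared regions (99.4%) the fold was higher in replicate 2, over an extent set largely by its own calls, which favours it. The number of shared regions was 3208 with 2 kb bins, 1586 with a fold minimum of 5 and 1443 when the overlap had to reach 50% of both regions.

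Replicate 2 had a far larger share of its reads in called regions than replicate 1. It gave 28150 regions over 293.8 Mb (11.2% of the span), against 7128 regions over 55.2 Mb (2.10%) in replicate 1. Regions held 49.3% of the reads of replicate 2 (95% Wilson interval 49.3 to 49.4) and 8.17% of those of replicate 1 (8.16 to 8.18), with a mean fold over the covered length of 7.08 and 3.88. Over the same 295.9 Mb called in either library, the shares were 49.5% of the reads of replicate 2 (49.4 to 49.5) and 22.7% of those of replicate 1 (22.6 to 22.7), at a mean fold of 7.05 and 2.01. Regions of replicate 2 made up 293.8 Mb of that length. It was thus chosen mainly for high counts in replicate 2, which favours that library in this comparison. The median region was 5 kb wide in both. The widest reached 333 kb in replicate 2 and 103 kb in replicate 1.

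Nearly all regions of replicate 1 overlapped a region of replicate 2 by at least 1 bp. Of the 7128 regions, 6927 (97.2%) did so and 201 did not. With the regions of replicate 2 moved along the chromosomes the overlap averaged 18.1% and reached at most 20.2% in 100 sets. When each overlap had to cover 50% of both regions, it was 20.2%, against a mean of 3.11% and at most 3.86% in the same moved sets. In the other direction, 17.9% of the regions of replicate 2 overlapped one of replicate 1. The 23104 regions called in replicate 2 alone, with a median fold of 4.08 there, had a median fold of 1.37 in replicate 1, and 85.9% of them were above background in that library. Moved regions had a median fold of 1.003 in replicate 1, at most 1.02 in any set, and 49.6% of them were above background.

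Levels in the libraries followed each other across the regions called in either and less so within the shared regions. Across 28152 regions called in either library, Pearson's r of the log2 folds was 0.56 and Spearman's rho 0.53. Within the 4938 shared regions r was 0.22 and rho 0.19. For read counts across 251269 bins of 10 kb with reads, r was 0.77 (log2 counts) and rho 0.74. Placeable sequence and copy number also enter these counts, so they do not measure the mark alone. Regions and bins are not independent replicates, so no p-value is given.

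**Figure D1:**
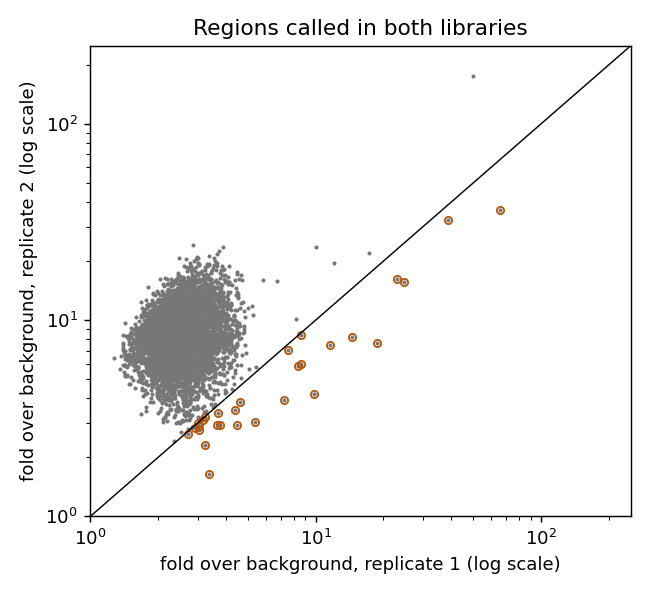
Fold over background of each of the 4938 shared regions in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale), with 1 grey point per region and the line of equal fold in black. Orange circles are the 29 regions whose fold in replicate 1 was at least that in replicate 2, and the other 4909 lie above the line.

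The 11 regions with the highest mean fold, 2 to 99 kb wide, were rich in reads with 2 placements, at no less than 25.4 times their genome-wide density in replicate 1 and 3.66 times in replicate 2. The highest, on chromosome 17 from 39451001 to 39457000, was 49.7-fold over background in replicate 1 and 176-fold in replicate 2 (mean log2 fold 6.55 ± 1.29 SD, n = 2). It held distinct positions of reads with 2 placements at 242 and 407 times their genome-wide density. Next came chromosome 5 from 3000001 to 3003000, with 65.7-fold and 36.6-fold (5.62 ± 0.60), and chromosome 2 from 98463001 to 98469000, with 38.6-fold and 32.3-fold (5.14 ± 0.18). At these intervals the density of reads with 2 placements was 1032 and 397 times, and 783 and 504 times, the genome-wide value. With repeated starts kept, the interval on chromosome 2 passed that on chromosome 17, at a mean log2 fold of 7.76 against 7.20. Chromosome 14 from 18208001 to 18211000 reached 24.6-fold and 15.6-fold, and chromosome 9 from 35054001 to 35056000 reached 23-fold and 16.1-fold. The widest of the 11, chromosome 11 from 3025001 to 3124000, covered 99 kb at 17.3-fold and 22.1-fold (4.29 ± 0.25), with reads of 2 placements at 60.8 and 83.9 times their genome-wide density. Of the 20 highest regions, 6 started below 4 Mb of their chromosome, 12 were narrower than 10 kb and 8 were 10 kb or wider, and 7 had a fold in replicate 1 at least as high as in replicate 2.

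Reads with 2 placements were less dense in the regions ranked 12, 13 and 16 to 20. In replicate 1 their density was at most 2.63 times the genome-wide value, below all of the 11 highest. In replicate 2 it was at most 14.6 times, where it overlapped the range of the 11. Ranks 14 and 15, on chromosomes 9 and 11, were rich in such reads like the 11 highest. Their densities were 185 and 76.1 times, and 34.2 and 29.3 times, in replicates 1 and 2. Chromosome 2 from 172862001 to 172930000, 68 kb wide, was 3.88-fold over background in replicate 1 and 23.7-fold in replicate 2 (3.26 ± 1.85, n = 2). Its density of reads with 2 placements was 0.464 and 4.25 times the genome-wide value. Chromosome 14 from 68194001 to 68243000 had 4.46-fold and 17.7-fold (3.15 ± 1.40), and chromosome 1 from 132878001 to 132926000 had 4.14-fold and 18.9-fold (3.14 ± 1.55). On chromosome 17, the 12 kb from 28817001 to 28829000 had 3.63-fold and 21.9-fold, and the 13 kb from 32902001 to 32915000 had 5.86-fold and 15.9-fold, with reads of 2 placements at 2.63 and 4.22 times their genome-wide density. On chromosome 5, the 7 kb from 48271001 to 48278000 held 0 reads with 2 placements and had a mean log2 fold of 3.16 ± 1.32.

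The longest shared regions took their length from replicate 2, which called 98.4% to all of each, while replicate 1 called between 1.89% and 90.1%. The longest, on chromosome 6 from 99161001 to 99494000, covered 333 kb at 2.07-fold in replicate 1 and 8.88-fold in replicate 2 (2.10 ± 1.49, n = 2), and replicate 1 called 33 kb of it. Chromosome 16 from 24306001 to 24610000 (304 kb) had 3.89-fold and 11.3-fold (2.73 ± 1.09) with 274 kb called in replicate 1, and chromosome 3 from 27610001 to 27904000 (294 kb) had 3.02-fold and 12.8-fold (2.64 ± 1.48) with 147 kb. Chromosome 8 from 123098001 to 123362000 (264 kb) had 1.49-fold and 7.55-fold with 5 kb called in replicate 1, and chromosome 15 from 52915001 to 53178000 (263 kb) had 3.38-fold and 10.2-fold with 221 kb.

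**Figure D2:**
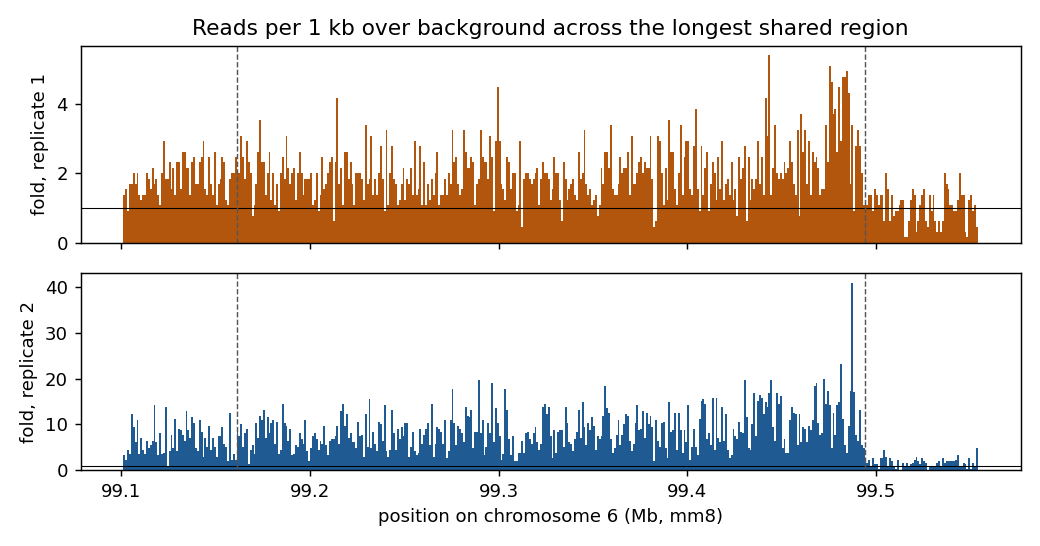
Reads per 1 kb bin over background (y axis, fold) along chromosome 6 (x axis, Mb, mm8) in replicate 1 above and replicate 2 below, with dashed lines at the ends of the longest shared region, 99161001 and 99494000, and a solid line at background. The mean fold across it was 2.07 in replicate 1 and 8.88 in replicate 2, and the y axes differ in scale.

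Among the autosomes and X, regions per Mb were highest on chromosomes 11 and 19 and lowest on X. Chromosome 11 held 4.47 regions per Mb in replicate 1 and 16.8 in replicate 2, and chromosome 19 held 3.96 and 14.2, against 2.87 and 11.3 over all autosomes. By the share of the chromosome covered, chromosome 11 was again the highest, at 3.40% and 18.5%, followed by chromosome 15 in replicate 1 (2.88%) and chromosome 17 in replicate 2 (15.3%). By regions per Mb, the lowest autosome was chromosome 12 in replicate 1 (1.97 per Mb) and chromosome 14 in replicate 2 (8.20). X held 0.338 regions per Mb in replicate 1 and 1.84 in replicate 2, in all 56 and 305 regions, and calls of both libraries met in 42 merged regions there. Reads per Mb on X relative to the autosomes were 0.508 in replicate 1 and 0.240 in replicate 2 (0.374 ± 0.190 SD, n = 2). In shares of nuclear reads, X took 3.30% (exact 95% interval 3.29 to 3.31) and 1.59% (1.58 to 1.59).

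Chromosome Y held 5440 distinct reads in replicate 1 and 1378 in replicate 2, and 2 shared regions. The mitochondrial genome held 4608 distinct starts in replicate 1, of which 41.9% (95% Wilson interval 40.5 to 43.3) were on the plus strand, and 565 in replicate 2, of which 46.9% (42.8 to 51.02) were. With repeated starts kept, the reads numbered 9664 and 652, and the plus strand held 31.0% and 46.9% of them.

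**Figure D3:**
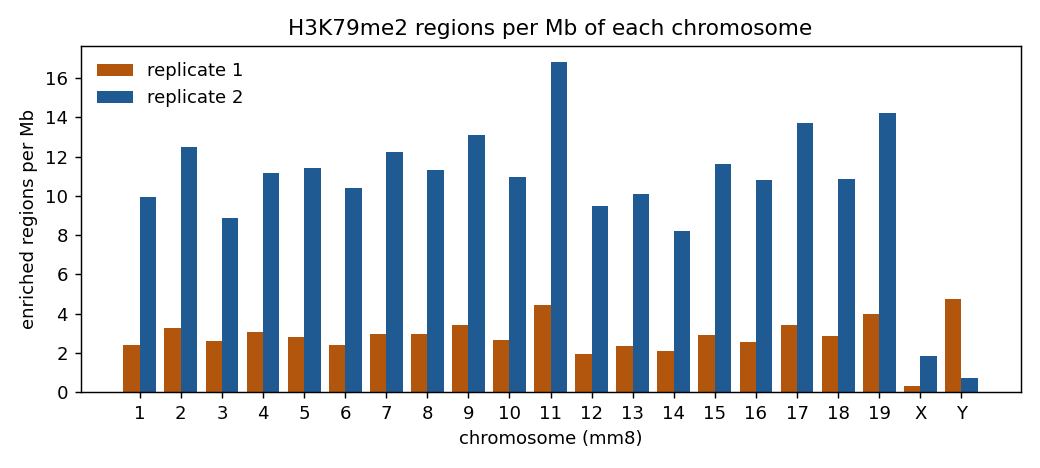
Enriched regions per Mb of observed span (y axis) for each chromosome of mm8 (x axis), with 1 bar for each replicate. Chromosome 11 has the highest autosomal bar in both replicates, at 4.47 and 16.8, while X stands at 0.338 and 1.84. The Y bar of replicate 1 rests on 13 regions and that of replicate 2 on 2.

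Large parts of the genome carried no region in either library. Of 2579 windows of 1 Mb on the autosomes and X, 602 (23.3%) held none, and on X 79 of 163 (48.5%) held none. The longest stretch without a region was on X from 77330001 to 90083000, 12.8 Mb, with reads in 80.8% of its bins in replicate 1 and a mean of 0.553 and 0.250 times background. X from 53137001 to 64939000 (11.8 Mb) and X from 109302001 to 119119000 (9.82 Mb) followed. X from 22878001 to 32320000 held reads in 8.31% of its bins in replicate 1. Bins on X were tested against the background of the whole genome. Reads far from regions stood there at 0.700 of the autosomes in replicate 1 and 0.537 in replicate 2. A bin on X therefore needed a larger rise over its surroundings to be called. On the autosomes the longest were chromosome 1 from 99927001 to 107183000 (7.26 Mb) and chromosome 16 from 65782001 to 72546000 (6.76 Mb).

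Relative to the reads that each library held in these regions, counts in 4655 of 28152 regions (16.5%) differed between the libraries beyond counting error. Those totals were 3861112 reads in replicate 1 and 6464269 in replicate 2, so the test asks which regions depart from the overall ratio of 0.597. Of the 4655, 2744 were higher in replicate 1 and 1911 in replicate 2, and with scaling by the median ratio over regions the split was 1941 against 2638. The median fold in replicate 2 was 4.74 for the 2744 and 9.93 for the 1911. Background was 2.10 times as high in replicate 1, and the counts compared include it. Background reads make up more of the count in weaker regions, so they move such regions toward replicate 1. A region counted as higher in replicate 1 therefore need not carry more of the mark there. The split itself also uses the counts of replicate 2. These values thus do not show whether direction went with the strength of the mark. Scaled by all distinct reads, 162 were higher in replicate 1 and 19235 in replicate 2, and scaled by background, 72 and 27262. On the scale of region totals, the largest ratios toward replicate 1 were on X from 52615001 to 52619000, with 85 reads against 3 (log2 ratio 5.35, exact binomial test, adjusted p = 2.74e-30), on chromosome 15 from 22987001 to 22990000, with 55 against 2 (5.22, adjusted p = 2.04e-19), and on X from 121644001 to 121646000, with 53 against 3 (4.68, adjusted p = 1.40e-17). Toward replicate 2 they were on chromosome 9 from 95214001 to 95217000, with 28 against 209 reads (log2 ratio -2.13, exact binomial test, adjusted p = 6.88e-17), and on chromosome 7 from 18116001 to 18118000, with 8 against 61 (-2.11, adjusted p = 3.61e-05), and from 118309001 to 118311000, with 8 against 55 (-1.96, adjusted p = 0.000242). Library, date, flow cell and gel range cannot be told apart here.

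The libraries shared few exact read starts. Of the distinct starts of replicate 2, 94896 (0.726%) were also present in replicate 1, against 0.603% from the density in 1 kb bins and 0.682% at offsets of up to 10 bp. The ratio to the neighbouring offsets was 1.06, and 1.07 outside regions. They were therefore counted as 2 libraries.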

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

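The counts in this part come from tests chosen after the data were seen. Reads with 2 placements were left out of the comparisons, and are listed here as signal outside them. In the 1 kb bin on chromosome 2 from 98467001 to 98468000 they piled up to 20299 lines in replicate 1 and 2209 in replicate 2, which was 1.63% and 0.287% of all such lines and the highest bin of both libraries. Across shared regions, leaving out the 29 whose fold in replicate 1 was at least that in replicate 2, the density of their distinct positions was 2.71 times that elsewhere in replicate 2 and 0.945 times in replicate 1.

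Among those 29 regions, 11 were at least 5-fold over background in both libraries, and their median density of reads with 2 placements was 185 times the genome-wide value in replicate 1 and 96.3 times in replicate 2. Of the other 18, 4 were also dense in such reads, at 37.0 to 223 times in replicate 1 and 9.57 to 46.1 times in replicate 2, and the remaining 14 reached at most 3.29 and 1.75 times. The median over the shared regions outside the 29 was 0.658 and 1.59 times.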

How the results depend on the processing

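Settings added after seeing the data are the fold minimums for regions, adding reads with 2 placements, 10 kb bins for agreement, scaling by all distinct reads or by background, and both settings for the shape of regions. Shared regions numbered 4938, and 3208 with 2 kb bins, 1443 with 50% overlap and 1586 at a fold minimum of 5. Leaving out a library gave 7128 to 28150 regions, the number of the remaining library alone. Replicate 1 gave 4162 regions with 2 kb bins and 2016 at a fold minimum of 5. Replicate 2 gave 16485 with the genome mean as background, and 17923 at adjusted p 1e-05 and again at a fold minimum of 5. The share of replicate 1 regions overlapping replicate 2 was 97.2%. It was 96.3% with all reads, 94.6% with the genome mean, 98.7% with replicate 1 thinned, 97.6% at adjusted p 1e-05, 99.0% with 2 kb bins, 95.4% with no gap, 20.2% with 50% overlap, 98.9% at a fold minimum of 5 and 96.7% with reads of 2 placements added. Spearman's correlation between libraries was 0.189 in shared regions and 0.735 for read counts in 10 kb bins. Scaling by the median ratio left 42.4% of differing regions higher in replicate 1, against 58.9%. Scaling by all distinct reads gave 19397 differing regions, 0.835% of them higher in replicate 1, and scaling by background gave 27334, with 0.263%, as these scalings do not take out the higher share of reads that replicate 2 has in regions. The ratio of X to the autosomes ran from 0.240 to 0.508 when either library was left out. In regions of at least 30 kb, 90.6% had the same higher end in both libraries. The cause was not tested for the other changes. With both libraries kept, another 42 values stayed between 0.694 and 1.40 times the main value. Some of them say nothing on stability. The number of regions of replicate 2 could not change when replicate 1 was thinned, and a fold minimum of 2 gave the main values again. Of the 25 regions named as highest or longest, 17 moved by less than the SD between libraries with all reads, 21 with the genome mean, and 25 under both other shifts and with replicate 1 thinned. That SD ran from 0.18 to 1.85 in log2 fold, as the libraries differ in enrichment. A move below it therefore does not show that a level was stable. The settings planned for marked genes, gene lists, position within genes and whole genes were not run, for want of gene coordinates of mm8. At the depth of replicate 2, simulated 10 kb regions at 4-fold were recovered in 24.0% of cases. This holds at the threshold set on the simulated counts, which can be stricter than that of the calls reported.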

Other observations

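The shape of regions, neighbouring regions and the tests of what lies behind the values of X and of replicate 1 were not part of the planned design. The tests of counting noise, of a single X copy, of sequencing depth and of regions thinned to matched reads were chosen after the result was seen, and the single-copy test replaced a first form that had admitted noise.

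Within wide shared regions, whose extent is largely that called in replicate 2, the mark leaned to one end. The higher end was taken as the side of a region's middle on which the mean position of its reads lay. In 3437 of 3972 shared regions of at least 10 kb on the autosomes and X, it was the same in both libraries (86.5%, exact 95% interval 85.4 to 87.6). Of the 3972, the left end was the higher in 49.9% in replicate 1 and 49.4% in replicate 2. In the 1564 regions of at least 30 kb, with the higher end taken from the other library, the outer 10 kb at that end had a mean fold of 2.98 in replicate 1 and 11.2 in replicate 2, against 1.83 and 6.09 at the opposite end. The signal was highest 6 to 7 kb inside the edge in replicate 1 (3.43-fold) and 5 to 6 kb inside it in replicate 2 (12.5-fold).

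Counting noise would give the same end in about 50% of regions, far from the 86.5% seen. A gradient in placeable sequence would act outside regions too. Intervals of the same widths moved to places without regions had the same higher end in 63.8% (exact 95% interval 62.3 to 65.3). This was 22.7 points below the regions, past the margin of 20 points set beforehand for that comparison. The moved intervals held fewer reads, however. Regions thinned to their read counts, a comparison added later, had it in 81.5% (exact 95% interval 80.2 to 82.7). That was 17.6 points above the moved intervals, a difference beyond counting error but short of the same margin. Such a gradient and base composition therefore stay open. A candidate explanation is that the higher end lies at the start of a transcribed gene, which was not tested for want of gene coordinates of mm8.

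If regions often came in divergent pairs, neighbours would face each other with their higher ends. Among 260 pairs less than 10 kb apart, drawn from the 3437 regions whose higher end was the same in both libraries, 54 did so, against a mean of 65.0 with ends assigned at random (95% range 52 to 79; permutation test, two-sided p = 0.119), so these data gave no sign of it. Pairs close enough to be merged into 1 region were not seen by this test.

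X held fewer regions per Mb than the autosomes in both libraries. If bins without placeable reads were the cause, the share of bins with reads would fall as far as the region density. That density was 17.2% of the lowest autosome in replicate 1. The share of bins with reads was 82.0% of the autosomal one in replicate 1, 59.2% in the shallower replicate 2 and 83.5% with both joined. Per Mb of bins with reads, X still stood at 20.96% of the lowest autosome in replicate 1 and 38.0% in replicate 2 (22.5% without that correction). These values argue against bins without reads as the whole cause. A bin with any reads counted alike, so fewer placeable positions within bins could still lower the calls, which was not tested. A single X copy may account for part of the lower region density. With autosomal reads thinned to 50% and all chromosomes tested against a background lowered alike, X stood at 60.7% of the lowest autosome in replicate 2. In replicate 1 it stood at 114%. There reads far from regions stood on X at 0.700 of the autosomes (0.537 in replicate 2), above that lowered background, which raises the 114%. A single copy therefore stays open. The sex of the embryos is not given in the labels used here, and no biological explanation other than copy number was tested.

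Replicate 1 gave fewer regions than replicate 2. Depth argues the other way, since replicate 1 had 1.30 times the distinct reads. If background reads diluted the same signal, the excess over background in regions of replicate 2 would be a constant share of that in replicate 2. Over 5 groups of regions by rising fold in replicate 2 it was 0.134, 0.130, 0.142, 0.170 and 0.170. The outer groups stood at a ratio of 1.27, and the share was 0.164 over all 27843 autosomal regions. The share was thus close across groups but not constant. Regions were also chosen and grouped by their fold in replicate 2, which affects it. Such group means therefore cannot decide on dilution, and they do not test it region by region. Across shared regions Spearman's rho between the libraries was 0.19. Antibody yield, gel range, date and flow cell cannot be separated with 1 library each.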
